A study of Mus musculus with 4 samples.

How the data were processed

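Polyadenylated RNA of colon tumour tissue was measured in 4 mouse libraries, 2 labelled Gsk3b IEC+/+ and 2 labelled Gsk3b IEC-/-. Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with an NEBNext Ultra kit, and paired reads were sequenced on a NovaSeq 6000. The submitters' processing notes name TopHat, limma, edgeR and the mm10 genome build, with no versions or roles. The counting tool, the annotation and the use of strand were not given in the sources used here. The deposited values are whole-number read counts per gene symbol, with no further normalization. Of the gene symbols, 20618 had a count in at least 1 library. Total counts per library were 25472503 to 27218515, so depth differed little between libraries. Groups and replicate numbers were taken from the sample titles.

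Genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with library sizes scaled by TMM (factors 0.955 to 1.05), the default expression filter of edgeR, and a quasi-likelihood F-test of IEC-/- against IEC+/+ with no other term. The filter kept 16637 genes. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p under 0.05, with a log2 fold change of at least 1 in either direction as a separate size limit. The common biological coefficient of variation was 0.248. Standard errors of log2 fold changes were derived from the F statistic, intervals cover 95%, and levels are in CPM of the scaled library sizes, given as mean ± SD over the 2 libraries of a group. Coordinates are those of RefSeq on GRCm38, the assembly also called mm10, in which 16616 of the genes tested were found by symbol.

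The 49 gene lists, with 1053 genes, were fixed before the data were examined. So were the tests of single genes and of lists, the rule for naming genes and most alternatives. The alternatives added later were the GC and length corrections and the estimated correlation with a library left out. The closing section says which of its tests were chosen after the results were seen. The lists cover epithelial and other cell types, signalling, immune and metabolic pathways and signs of RNA quality. Members were matched by symbol or by a single RefSeq synonym, which left 35 genes unmatched; the list of mitochondrially encoded mRNAs had no matched gene and was not analysed here, nor were immunoglobulin or T cell receptor constant genes. Lists with at least 5 genes tested were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 48 lists, and with an estimated correlation, fry and cameraPR as alternatives. Of these, fry asks whether a list changed at all, without comparing it with other genes. Named genes were Gsk3b, Gsk3a, Ctnnb1, Xist and Ddx3y; the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap and whose higher group averaged at least 1 CPM, without unnamed models or immune receptor segments; and the members with the smallest p, up to 4, in each called list and in the Wnt target, stem cell, proliferation, goblet and colonocyte lists. A few others are named in the closing section, where it is said that they were chosen after their values were seen.

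Libraries were compared before averaging. The chi-square statistic of the counts per degree of freedom was 35.4 between the IEC+/+ libraries, 70.0 between the IEC-/- libraries and 92.8 to 135 between libraries of different groups, so no library was a repeat of another. The first principal component of log2 levels held 52.5% of the variance. On it the IEC+/+ libraries lay at -51.2 and -26.1 and the IEC-/- libraries at 16.7 and 60.5. It thus ordered the libraries by group but also spread those of the same group. The second held 30.0% and separated the IEC-/- libraries from each other. By Pearson correlation of log2 levels, IEC-/- replicate 1 was no closer to IEC-/- replicate 2 (0.9589) than to IEC+/+ replicates 1 and 2 (0.9592 and 0.9643). For 55 genes with at least 100 counts in total, another gene had identical counts in all 4 libraries, among them near-identical copies and different genes that share a locus or exons. How the counting treated shared reads was not given in the sources used here, and 0 of these genes were among the changed genes. Named genes known to have close paralogs are reported as uncertain. In the haemoglobin list, Hbb-b2 and Hbb-bt had identical counts, and Hbb-bs and Hbb-b1 nearly so (2239 and 2232 in IEC+/+ replicate 1). That list therefore counts nearly the same values more than once.

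The test was checked on simulated counts drawn from the means, dispersions and library sizes of these 4 libraries, with 200 of 16637 genes changed in each of 5 runs. It called 25.6% of genes changed by a log2 of 1, 80.8% at 2, 96.0% at 3 and 99.2% at 4, and 0.120% of unchanged genes. Over the 5 runs these calls were 64, 202, 240 and 248 of 250 changed genes at each size, and 97 of 81032 unchanged genes. False calls were thus a larger share of all calls than the adjusted p limit sets. The alternatives tried were RLE and upper-quartile scaling, no filter and a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, edgeR's exact test, the replicate number as a block, each library left out, immunoglobulin, T cell receptor, haemoglobin and mitochondrial genes left out, and adjusted p limits of 0.01 and 0.1. Corrections of each library for transcript GC content and transcript length, by loess with a span of 0.3 on the longest GENCODE M21 transcript, were added after seeing the data; 96.7% of the genes tested and 97.3% of the changed genes had a value. Figures were drawn with matplotlib 3.10.9.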

Results

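The expression profiles of 4 mouse colon tumour samples were compared to ask how loss of GSK3B from the intestinal epithelium alters the transcriptome of chemically induced colon cancer. GSK3B is a serine/threonine kinase of the complex that marks beta-catenin for degradation. Tumours had been raised with azoxymethane, a carcinogen, and dextran sulfate sodium, which injures the colonic epithelium. The labels name 2 groups of 2 libraries, IEC+/+ and IEC-/-, for the Gsk3b state of the intestinal epithelial cells. Polyadenylated RNA of tumour tissue was sequenced from each sample. The deposited values are read counts per gene symbol. Total counts were 27135796 and 27218515 in IEC+/+ replicates 1 and 2, and 26599419 and 25472503 in IEC-/- replicates 1 and 2. The labels do not say whether the libraries of a group came from separate mice, so p-values measure only the spread between these samples.

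Gsk3b mRNA was present at similar levels in all 4 libraries. Gsk3b (chromosome 16, 38089001 to 38246084, GRCm38) had 170 and 157 CPM (counts scaled to a common library size) in the IEC+/+ libraries and 152 and 149 CPM in the IEC-/- libraries. The group means were 164 ± 9.53 and 151 ± 2.41 CPM (SD, n = 2 each), a log2 fold change of -0.12 (SE 0.12, edgeR quasi-likelihood adjusted p = 0.681). The 95% interval of the IEC-/- to IEC+/+ ratio was 0.751 to 1.13. The labels do not say which exons were deleted, and the tissue holds cells other than epithelium, so the gene count does not check the labels. The groups are therefore called the libraries labelled IEC+/+ and IEC-/-. Gsk3a, the paralogous kinase, had mean levels of 106 ± 5.87 and 96.9 ± 3.96 CPM (log2 fold change -0.13, adjusted p = 0.651). Ctnnb1, which encodes beta-catenin, had 1699 ± 36.1 and 1874 ± 41.1 CPM (0.14, adjusted p = 0.599). Ddx3y, a Y-linked gene, was counted 1829 to 2337 times per library and Xist 4 to 22 times, as in male tissue.

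Most genes that changed were lower in the libraries labelled IEC-/-. Aqp8, a water channel, had 12.6 ± 6.91 CPM in IEC+/+ and 0.293 ± 0.145 CPM in IEC-/- (SD, n = 2 each), and Clca4a, of the chloride channel regulator family, had 158 ± 78.4 and 4.08 ± 1.35 CPM. Of 16637 genes tested, 147 changed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 20 higher and 127 lower, so that 86.4% of them were lower. At least a 2-fold change was seen for 138 of these, 18 higher and 120 lower, and 50 fell at least 4-fold. At an unadjusted p under 0.05, 1247 genes were higher and 1517 lower, and the median log2 fold change over all genes was 0.01. All 147 genes had groups that did not overlap in CPM, which chance gives for 1 gene in 3 with 2 libraries against 2. Such groups can hardly reverse when the same libraries are refitted or 1 is left out, so directions kept below are no further support. The smallest adjusted p was 0.0322, so no gene passed 0.01. Leaving out either IEC+/+ library, which leaves a lone library assumed to vary like the others, ended every call by edgeR: 0 genes changed without replicate 1 (1384 at an unadjusted p under 0.05) and 0 without replicate 2 (1754), although all 147 kept their direction. The count was 729 without IEC-/- replicate 1 (344 higher and 385 lower, so 52.8% lower) and 567 without IEC-/- replicate 2 (169 and 398), with all 147 genes called again, and by other tools on all libraries it was 1293 (DESeq2), 869 (exact test of edgeR) and 78 (limma-voom).

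**Figure D1:**
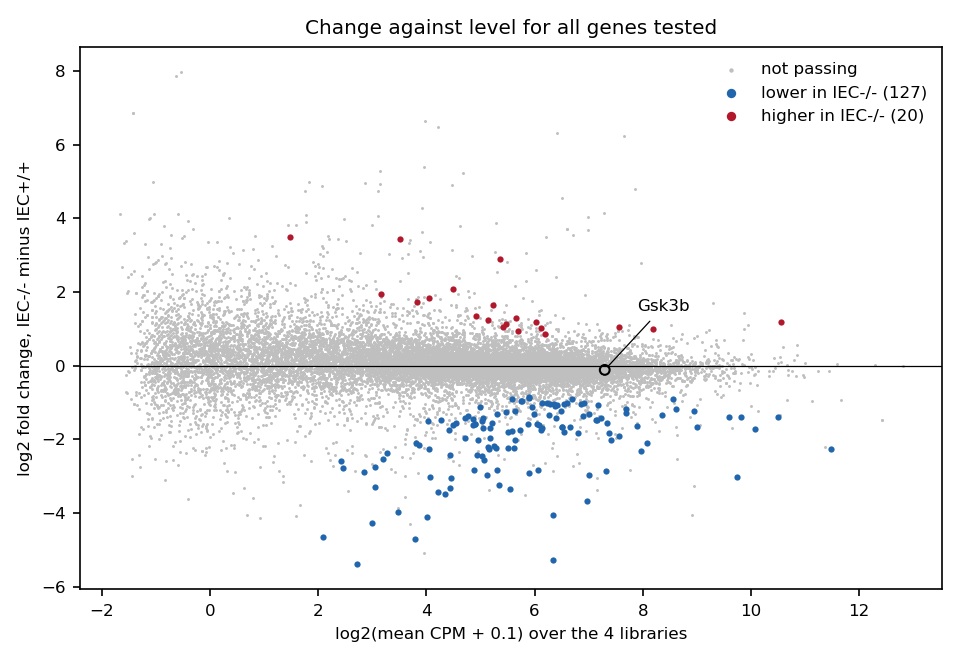
Log2 fold change of IEC-/- over IEC+/+ against the log2 mean CPM for the 16637 genes tested. Coloured points are the 20 genes higher and the 127 genes lower at an adjusted p under 0.05, and the ring marks Gsk3b, at a log2 fold change of -0.12.

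The 10 largest named falls were 11.2-fold to 42.2-fold. After Aqp8 (log2 fold change -5.40, SE 0.63, adjusted p = 0.0413) and Clca4a (-5.28, SE 0.46, adjusted p = 0.0403) came Sycn, which encodes syncollin, a secretory granule protein, with 26.3 ± 4.26 CPM in IEC+/+ and 0.993 ± 0.326 CPM in IEC-/- (-4.72, SE 0.33). Slc13a2, a sodium-coupled dicarboxylate transporter, had 14.9 ± 0.290 and 0.769 ± 0.387 CPM (-4.26, SE 0.42), and Slc13a2os, which overlaps it on chromosome 11 and is annotated as its opposite strand, had 7.98 ± 1.87 and 0.314 ± 0.0132 CPM (-4.64, SE 0.42). The counting is not stated to use strand, so reads of this pair cannot be told apart. Slc15a1, the intestinal peptide transporter, had 20.7 ± 5.26 and 1.31 ± 0.0769 CPM (-3.97, SE 0.31). The gasdermin C genes Gsdmc3 and Gsdmc4 had log2 fold changes of -4.10 and -3.68. Ly6m and the serine protease gene Prss30 had -4.06 and -3.49. Gsdmc3, Gsdmc4, Ly6m and Clca4a have close paralogs, and how reads were shared among these was not stated, so their separate values are uncertain. Adjusted p-values of the 10 genes lay between 0.0322 and 0.0413.

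Among the rises, Chrm3, the muscarinic acetylcholine receptor M3, had 0.440 ± 0.0332 CPM in IEC+/+ and 4.95 ± 0.491 CPM in IEC-/- (log2 fold change 3.48, SE 0.41, adjusted p = 0.0428). Alb, which encodes albumin, had 9.65 ± 0.540 and 72.2 ± 23.5 CPM (2.90, SE 0.26, adjusted p = 0.0403), and the transcription factor gene Sox2 rose 3.81-fold (1.93, SE 0.24, adjusted p = 0.0461). Aox4, an aldehyde oxidase gene, rose 3.53-fold, Prom2, which encodes a membrane protrusion protein, 3.28-fold, and the transcription factor gene Arnt2 3.15-fold. Mdga2, Mark1, Pdzrn3 and Podn rose 2.29-fold to 2.53-fold.

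**Figure D2:**
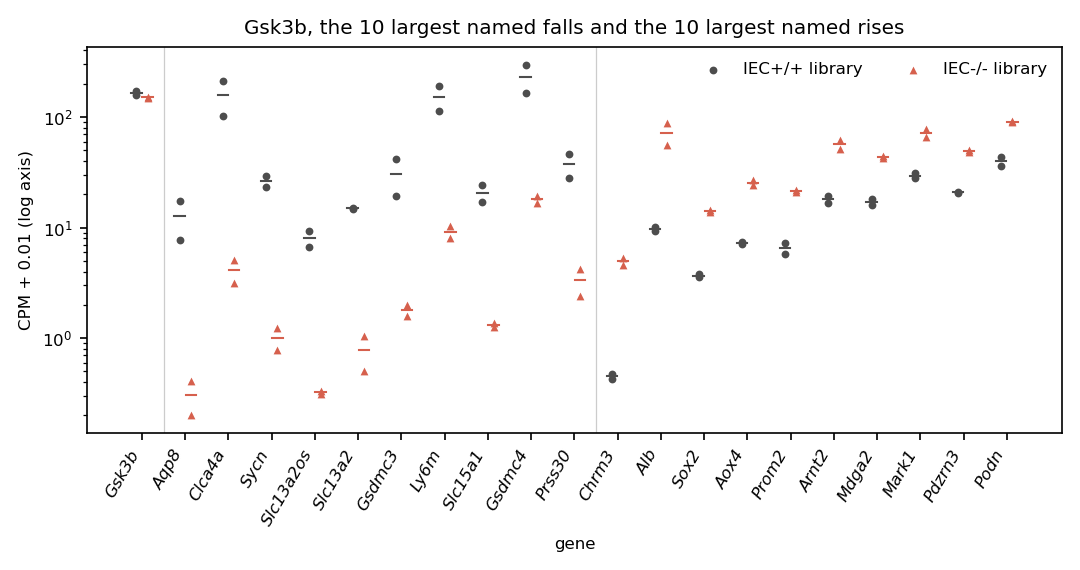
CPM plus 0.01 on a log axis for Gsk3b, the 10 largest named falls and the 10 largest named rises, with 1 point per library and bars at the group means. Gsk3b lies between 149 and 170 CPM in all 4 libraries, and the groups do not overlap for any of the other genes.

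Fixed gene lists were then compared with all other genes by camera. Of 48 lists with at least 5 genes tested, 20 were called at an adjusted p under 0.05, 15 lower and 5 higher in IEC-/-. With a correlation estimated for each list 0 were called by camera (0 of 48 at an unadjusted p under 0.05), and the adjusted p of these 20 lists then lay between 0.647 and 0.691. By fry, 0 lists were called as moving in 1 direction (9 at an unadjusted p under 0.05) and 8 as changing in either direction. Of these 8, 3 were among the 20 called by camera (glycolysis and hypoxia, oxidative phosphorylation and T cell genes) and 5 were not. Those 5 were fatty acid oxidation and PPAR target (fry adjusted p for either direction 0.00251) and epithelial-mesenchymal transition genes (0.0196), stem and crypt base cell (0.0423) and NF-kappaB target genes (0.0423), and Wnt ligands, receptors and destruction complex (0.0441). In simulated data with 2 libraries per group, a list of 20 genes shifted by a log2 of 1 was called in 5 of 5 runs with the preset correlation and in 0 of 5 with the estimated correlation. The simulated genes were drawn independently, so these runs do not show how the preset correlation behaves on correlated lists. In the real data the estimated correlation of the called lists ran from 0.0124 (histone genes) to 0.979 (MHC class I genes). Of the 20 lists, 10 were called again whichever library was left out.

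Genes of differentiated colonocytes were the lowest of the lists in IEC-/-. Of 25 genes tested, 6 fell over all genes tested, 17 fell adjusted over the list alone, and 19 did not pass over all genes. The median log2 fold change was -1.91 (camera adjusted p = 2.37e-27; adjusted p = 0.647 with an estimated correlation). Besides Clca4a and Aqp8, Slc5a8, a transporter of short-chain fatty acids, fell from 73.1 ± 32.1 to 7.79 ± 1.92 CPM (log2 fold change -3.23, SE 0.37, adjusted p = 0.0413), and Mep1a, which encodes a brush border protease, fell from 53.3 and 25.1 CPM in the IEC+/+ libraries to 4.28 and 3.55 CPM in IEC-/- (-3.32, SE 0.41, adjusted p = 0.0461). The IEC+/+ libraries also differed between themselves, the list median lying 0.93 higher on the log2 scale in replicate 1 than in replicate 2. Smooth muscle genes, a list that was not called (adjusted p = 0.0976), were 1.01 higher in that same library, and both IEC-/- libraries lay below both IEC+/+ libraries in the colonocyte median. Heat shock and immediate-early genes, lists fixed as signs of sample handling, were also lower in IEC-/-, with medians of -0.63 and -0.40. In both, 0 genes passed over all genes tested (camera adjusted p = 0.675 for each list with an estimated correlation).

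Goblet cell genes were lower as well. Of 20 tested, 3 fell over all genes tested, 11 fell adjusted over the list alone and 18 had lower means in IEC-/- (median -0.86; camera adjusted p = 1.45e-14; adjusted p = 0.647 with an estimated correlation). Fcgbp, which encodes a mucus protein, fell from 1523 ± 615 to 185 ± 14.1 CPM (log2 fold change -3.04, SE 0.30, adjusted p = 0.0403), the trefoil factor gene Tff3 from 184 ± 29.9 to 73.5 ± 4.57 CPM (-1.32, SE 0.16), and Galnt12, which starts mucin-type O-glycans, from 62.9 ± 2.69 to 26.1 ± 1.33 CPM (-1.27, SE 0.12). Clca1 did not pass, with 1375 and 452 CPM in IEC+/+ against 40.8 and 68.8 CPM in IEC-/- (adjusted p = 0.0588). In the xenobiotic metabolism list 5 of 25 genes fell over all genes tested and 8 adjusted over the list alone (median -1.10; camera adjusted p = 1.21e-11; adjusted p = 0.647 with an estimated correlation). Cyp4f14 fell 6.76-fold, Cyp2d34 5.37-fold and Sult1b1 5.53-fold, and the carboxylesterase gene Ces2c fell 10.8-fold, with close paralogs again leaving Cyp4f14, Cyp2d34 and Ces2c uncertain. General epithelial genes had a smaller shift, with 1 of 20 falling over all genes tested, 9 adjusted over the list alone, and a median of -0.31 (camera adjusted p = 5.33e-06; adjusted p = 0.647 with an estimated correlation). That gene was Lgals4, a galectin gene whose paralog Lgals6 shares its sequence closely, at 1309 ± 172 and 499 ± 3.62 CPM. Krt19, Cdh17 and Tspan8 did not pass, with log2 fold changes of -0.95, -1.01 and -1.29.

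Wnt/beta-catenin target genes were higher in IEC-/- as a list, by less than 2-fold. By edgeR 0 of the 29 genes passed over all genes tested (12 higher and 2 lower at an unadjusted p under 0.05), and 11 rose and 1 fell adjusted over the list alone. By DESeq2 11 were higher and 1 lower, by the exact test 5 and 1, and by limma-voom 0. Means were higher in IEC-/- for 22 genes (median 0.33; camera adjusted p = 0.000712; adjusted p = 0.647 with an estimated correlation). Axin2, a feedback inhibitor of the pathway, had 410 and 447 CPM in IEC+/+ and 670 and 654 CPM in IEC-/- (log2 fold change 0.63, SE 0.12, adjusted p = 0.0851). The Dickkopf family gene Dkk3 and the secreted antagonist genes Wif1 and Notum had log2 fold changes of 0.75, 0.74 and 0.67 (adjusted p = 0.0613, 0.0874 and 0.0903). Intestinal stem and crypt base cell genes moved both ways, 5 of 18 rising and 4 falling adjusted over the list alone (camera adjusted p = 0.749). Over all genes tested 0 passed by edgeR (6 higher and 4 lower at an unadjusted p under 0.05), 8 by DESeq2, 2 by the exact test and 0 by limma-voom. In that list Smoc2 and Mex3a had log2 fold changes of 0.72 and 0.53 (adjusted p = 0.13 and 0.147), and Aqp4 and Clca4b, the latter uncertain as a paralog of Clca4a, had -1.43 and -2.54 (adjusted p = 0.0754 and 0.0762). Proliferation genes had a median of -0.05, with 0 of 32 passing by edgeR (1 at an unadjusted p under 0.05), DESeq2, the exact test or limma-voom. The camera adjusted p was 0.502, and without IEC-/- replicate 1 the list was called lower (adjusted p = 0.0171; adjusted p = 0.748 with an estimated correlation). Pcna had 178 ± 5.46 and 157 ± 12.7 CPM, and Birc5, Uhrf1 and Ccne2 had log2 fold changes of -0.27, -0.27 and -0.48 (adjusted p = 0.441, 0.521 and 0.279). The list of Wnt ligands, receptors and destruction complex genes was not called by camera (median 0.14, adjusted p = 0.519).

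Glycolysis and several other stress and metabolic lists were called lower in IEC-/-, mostly without single genes passing by edgeR. Glycogen metabolism (median -0.02, camera adjusted p = 0.519), fatty acid oxidation and PPAR target (-0.28, 0.0976) and p53 target and cell death genes (-0.20, 0.206) were not called by camera. By cameraPR on ranks the fatty acid oxidation list was called lower (adjusted p = 0.00630) and the glycogen and p53 lists were not. The heat shock and immediate-early lists, among those called lower by camera, had been fixed as signs of sample handling. They differed between the groups together with the epithelial lists. In the heat shock, unfolded protein response, NRF2, oxidative phosphorylation, cholesterol and immediate-early lists 0 genes passed over all genes tested. At an unadjusted p under 0.05 these had 11, 15, 10, 8, 6 and 6 lower and 0 higher genes. DESeq2 called 8, 10, 7, 2, 1 and 3 of them lower, the exact test 4, 3, 5, 0, 0 and 3, and limma-voom 0. Glycolysis and hypoxia genes had 2 of 26 falling over all genes tested and 10 adjusted over the list alone (median -0.34; camera adjusted p = 2.86e-05; adjusted p = 0.647 with an estimated correlation). These were Car9, a hypoxia-induced carbonic anhydrase gene, at 48.3 ± 1.35 and 16.9 ± 2.92 CPM (log2 fold change -1.52, SE 0.17, adjusted p = 0.0413), and the hexokinase gene Hk2, at 287 ± 36.5 and 127 ± 9.34 CPM (-1.17, SE 0.14, adjusted p = 0.0461). Egln3 and Pfkp had -0.97 and -0.66 (adjusted p = 0.0604 and 0.138). Heat shock genes had 11 of 16 falling adjusted over the list alone (median -0.63; camera adjusted p = 8.48e-08; adjusted p = 0.675 with an estimated correlation). IEC+/+ replicate 2 was highest, with Hspa1b, uncertain beside its near-identical copy Hspa1a, at 162 and 596 CPM in IEC+/+ and 55.6 and 51.5 CPM in IEC-/-. Unfolded protein response genes had 7 of 26 falling adjusted over the list alone (median -0.54; camera adjusted p = 1.24e-06; adjusted p = 0.675 with an estimated correlation), with the endoplasmic reticulum chaperone gene Hspa5 at 1410 ± 429 and 653 ± 55.7 CPM. NRF2 target genes had 7 of 22 falling adjusted over the list alone (median -0.37; camera adjusted p = 3.15e-05; adjusted p = 0.647 with an estimated correlation), among which Txnrd1 and Pgd had log2 fold changes of -0.66 each. Oxidative phosphorylation genes encoded in the nucleus were lower for 29 of 32, with 0 passing adjusted over the list alone (median -0.25; camera adjusted p = 0.00141; adjusted p = 0.647 with an estimated correlation), with Cox5a at 123 ± 1.58 and 82.5 ± 4.86 CPM. Cholesterol biosynthesis genes were lower for 21 of 24 (median -0.26; camera adjusted p = 0.00657; adjusted p = 0.691 with an estimated correlation), a call lost without IEC+/+ replicate 1 (0.106) and without IEC-/- replicate 1 (0.0785). Immediate-early genes had 3 of 22 falling adjusted over the list alone (median -0.40; camera adjusted p = 0.000412; adjusted p = 0.675 with an estimated correlation), with Klf6 at 257 ± 72.4 and 101 ± 0.132 CPM, and lost the call without IEC-/- replicate 1 (0.0775).

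Epithelial defence genes and regenerative genes were called lower as lists by camera, and the IEC-/- libraries differed from each other in both. In the antimicrobial and defence list means were lower in IEC-/- for 11 of 20 genes and higher for 9. In that list 2 fell over all genes tested and 6 fell and 1 rose adjusted over the list alone (median -0.29; camera adjusted p = 0.000740; adjusted p = 0.647 with an estimated correlation). Duoxa2, the maturation factor of an epithelial hydrogen peroxide producing oxidase, fell from 107 ± 6.83 to 31.7 ± 7.05 CPM (adjusted p = 0.0413), and the serum amyloid gene Saa1, whose paralog Saa2 leaves its value uncertain, from 229 ± 3.72 to 28.9 ± 15.7 CPM (adjusted p = 0.0472). This list lay 0.83 below the IEC+/+ mean in IEC-/- replicate 1 and 0.21 above it in replicate 2 on the log2 scale, and lost its call by cameraPR on ranks (adjusted p = 0.275) and without IEC+/+ replicate 2 (adjusted p = 0.909). Of 21 regenerative and fetal-like epithelial (YAP) genes, 1 fell over all genes tested, and 8 fell and 2 rose adjusted over the list alone (median -0.27; camera adjusted p = 0.00279; adjusted p = 0.675 with an estimated correlation). That gene was Anxa3, at 130 ± 12.7 and 63.6 ± 3.82 CPM, and the list lost its call without IEC-/- replicate 1 (adjusted p = 0.358).

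MHC class I presentation genes were higher in IEC-/- replicate 2 alone. H2-Q4 had 47.6 and 53.6 CPM in IEC+/+, 65.9 CPM in IEC-/- replicate 1 and 318 CPM in IEC-/- replicate 2. Nlrc5, the transactivator of class I genes, had 5.71, 7.19, 7.80 and 93.9 CPM in the same order. Against the IEC+/+ mean the list median was -0.03 in IEC-/- replicate 1 and 2.11 in replicate 2 on the log2 scale, with 0 of 17 genes passing by edgeR over all genes tested or adjusted over the list alone (5 at an unadjusted p under 0.05), and 0 by DESeq2, the exact test or limma-voom. The list was called higher (camera adjusted p = 0.000862; adjusted p = 0.691 with an estimated correlation), and without IEC-/- replicate 2 its direction was lower with an adjusted p of 0.965. H2-Q4 shares its sequence closely with other class I genes, so its own value is uncertain.

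Other immune lists had smaller shifts. Macrophage and monocyte genes were higher for 18 of 22 (median 0.49; camera adjusted p = 0.00390; adjusted p = 0.675 with an estimated correlation), with Itgam at 25.2 ± 1.40 and 38.2 ± 0.628 CPM. MHC class II genes were higher for 11 of 13 (median 0.66; camera adjusted p = 0.0226; adjusted p = 0.675 with an estimated correlation), with H2-Ab1 at 116 ± 17 and 204 ± 44.9 CPM. T cell genes were higher for 16 of 19 (median 0.37; camera adjusted p = 0.0439; adjusted p = 0.675 with an estimated correlation), where Tcf7, also a member of the Wnt target list, had 63.9 ± 0.376 and 89.0 ± 8.14 CPM. In these 3 lists 0 genes passed by edgeR, over all genes tested or adjusted over the list alone. At an unadjusted p under 0.05 they had 8, 4 and 3 higher genes. DESeq2 called 2, 3 and 1 higher, the exact test 0, 1 and 0, and limma-voom 0. Without IEC+/+ replicate 2 the macrophage call was lost (adjusted p = 0.0996), as were the MHC class II and T cell calls (0.262 for both). The MHC class II call was also lost without IEC-/- replicate 2 (0.0864), and the T cell call without IEC-/- replicate 1 (0.0695) or replicate 2 (0.0732). Haemoglobin genes, a sign of blood in the sample, were called lower (median -0.94 over 7 genes; camera adjusted p = 0.0329; adjusted p = 0.691 with an estimated correlation), with Hba-a2, uncertain beside its near-identical copy Hba-a1, at 169 and 387 CPM in IEC+/+ and 181 and 83.9 CPM in IEC-/-, and lost the call without IEC+/+ replicate 2 (0.713) or IEC-/- replicate 2 (0.358). Replication-dependent histone genes, whose reads reflect how strictly polyadenylated RNA was selected, were called lower (median -0.47 over 24 genes; camera adjusted p = 0.0478; adjusted p = 0.647 with an estimated correlation) and lost the call without IEC+/+ replicate 1 (0.106), IEC-/- replicate 1 (0.0785) or IEC-/- replicate 2 (0.255).

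**Figure D3:**
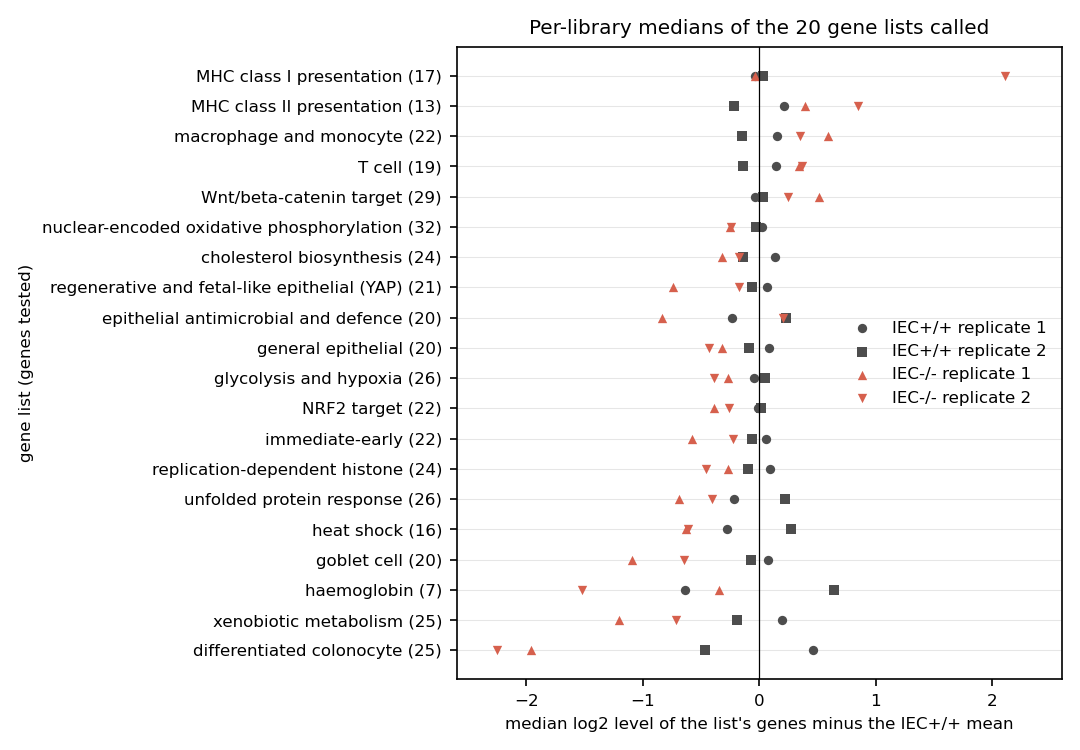
Median log2 level of the genes of each of the 20 called lists in each library, minus the mean of the IEC+/+ libraries, with the number of genes tested in brackets. Differentiated colonocyte genes lie at -1.96 and -2.25 in IEC-/- replicates 1 and 2, and MHC class I genes at -0.03 and 2.11.

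The other 28 lists were not called, with camera adjusted p-values from 0.0552 to 0.954. Endothelial genes (median 0.23, adjusted p = 0.0552), tuft cell genes (0.37, 0.0669), interferon-stimulated genes (0.56, 0.0687) and Notch pathway genes (0.23, 0.0922) were nearest to the threshold. With 1 library left out, 16 of the 28 were called in at least 1 fit with the preset correlation. By camera with an estimated correlation 0 lists were called in these fits (2 at an unadjusted p under 0.05 over the 4 fits), and the adjusted p of the lists gained then lay between 0.654 and 0.887. The interferon-stimulated list, at -0.63 in IEC-/- replicate 1 and 1.08 in replicate 2, was called higher without replicate 1 and lower without replicate 2, as were the squamous epithelial and the B and plasma cell lists. The signs differed for the neutrophil list, with a median of 0.21, a mean of 0.43 and a camera direction of lower, and for the pancreatic and small intestinal and the enteroendocrine lists, with medians of 0.00 and 0.01, means of -0.53 and -0.48 and a direction of lower. Medians were -0.19 for fibroblast and collagen genes, 0.15 for epithelial-mesenchymal transition genes, -0.06 for inflammatory cytokines and chemokines, -0.10 for NF-kappaB targets and 0.25 for Hedgehog and BMP pathway genes. With the preset correlation the cytokine list was called lower without IEC-/- replicate 2 (adjusted p = 6.26e-14; adjusted p = 0.654 with an estimated correlation) and without IEC+/+ replicate 1 (0.0185; 0.815). The fibroblast list was called lower without IEC+/+ replicate 2 (4.66e-05; adjusted p = 0.887 with an estimated correlation) and without IEC-/- replicate 1 (0.0238; 0.766).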

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

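The GC and length corrections, and the estimated correlation with a library left out, were chosen after seeing the data; the other alternatives were fixed before the data were examined. Against 147 changed genes (20 higher, 127 lower, 138 at least 2-fold), no filter gave 376 (69, 307 and 284), DESeq2 1293 (482, 811 and 623), edgeR's exact test 869 (308, 561 and 603), limma-voom 78 (10, 68 and 77) and the length correction 63 (8, 55 and 61). An adjusted p limit of 0.01 gave 0 changed genes (0 higher, 0 lower), against 2764 at an unadjusted p under 0.05, and a limit of 0.1 gave 510 (123 and 387). Leaving out each library in turn gave 0 to 729 changed genes, 0 to 344 higher, 0 to 398 lower and 0 to 613 at least 2-fold, with 0 without either IEC+/+ library; fewer samples were then tested, and the cause of the higher counts was not tested. In each fit with a library left out, the spread came only from the group that still had 2 libraries. The chi-square statistic of the counts per degree of freedom was 35.4 between the IEC+/+ libraries and 70.0 between the IEC-/- libraries. Calls kept without an IEC-/- library thus rest on the IEC+/+ spread alone. The cause of the other moves was not tested, except that adjusted p-values of the 147 genes lay between 0.0322 and 0.0494, so small shifts end calls. RLE scaling kept 143 of the 147 genes as calls, upper-quartile scaling 105, the GC correction 116, limma-voom 78 and the length correction 62, while DESeq2, the exact test, no filter and the 1 CPM filter kept all 147. All 147 kept their direction under each of these, which their non-overlapping groups largely fixed in advance. DESeq2 gave no adjusted p for 968 genes, and lower calls were 62.7% of its total against 86.4%. Replicate numbers are shared by the groups, and the labels do not say that they pair samples. Across genes the replicate differences of both groups correlated by r = 0.16. With the number as a replicate block there were 211 changed genes (38 higher, 173 lower), of which 125 were among the 147, and 16 gene lists called. The 4 calls lost were MHC class II (adjusted p = 0.0503), T cell (0.0627), haemoglobin (0.0927) and histone genes (0.0679). By cameraPR on ranks 26 gene lists were called, with 19 of the 20 kept and the antimicrobial and defence list lost. No filter gave 25, the length correction 22, RLE scaling and the GC correction 20 each, all keeping the 20, and leaving out immunoglobulin, T cell receptor, haemoglobin and mitochondrial genes 19 of 47, with haemoglobin genes not tested. Leaving out those classes removed few genes, with 16628 tested against 16637, so it checks little beyond haemoglobin. Gene lists called numbered 0 with an estimated correlation, 0 by fry and 8 by fry for either direction, against 20, 18 to 26 with each library left out, and 0 in each of those fits with an estimated correlation (2 at an unadjusted p under 0.05 over the 4 fits). Gsk3b kept its direction and did not pass under any alternative. Xist, at 4 to 22 counts, ranged from -1.79 to 0.96 with each library left out, reversing without IEC+/+ replicate 2 (0.96) and without IEC-/- replicate 2 (0.49). Ddx3y ranged from -0.038 to 0.19, reversing without IEC-/- replicate 1 (-0.038). Neither passed, and the cause was not tested. For all named genes other than Gsk3b, those that passed kept their call in 407 results and lost it in 118, and those that did not pass stayed so in 991, passed in 123 and reversed in the 3 of Xist and Ddx3y. The pseudocount alternative was not run, since the values are counts. In simulated data of this depth and size 25.6% of genes changed by a log2 of 1 were called, so changes near 2-fold may often be missed. In the same simulated data false calls were a larger share of all calls than the adjusted p limit sets. The share of false calls among the 147 genes may therefore also exceed that limit. The simulation drew genes independently and changed 200 of 16637, while 2764 genes had an unadjusted p under 0.05 in the data. Its shares of missed and of false calls need not hold for these data.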

Other observations

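All tests in this part were chosen after the result was seen, except that of genes near Gsk3b. The IEC-/- libraries differed from each other in immune and squamous genes, which the group comparison averages. In IEC-/- replicate 1 the median of 24 inflammatory cytokine and chemokine genes stood at -1.53 against the IEC+/+ mean on the log2 scale, and that of B and plasma cell genes at -0.73. In IEC-/- replicate 2 the same medians were 0.31 and 1.06. Interferon-stimulated genes were at -0.63 and 1.08. Squamous epithelial genes were at -1.24 and 2.87, with Krt5 at 0.193 and 10.4 CPM in IEC+/+ and 0 and 795 CPM in IEC-/-, and Krt14 at 77.6, 49.0, 13.0 and 863 CPM; both were chosen after their values were seen. Between the IEC+/+ libraries, replicate 1 had higher smooth muscle genes, by a median of 1.01 on the log2 scale, and replicate 2 higher heat shock genes, by 0.55. Eif2s3y, Y-linked, had 44.6, 48.7 and 66.0 CPM in 3 libraries and 7.16 CPM in IEC-/- replicate 1, and Erdr1 had 154, 154 and 220 CPM in 3 libraries and 15.0 CPM in IEC-/- replicate 2; these too were chosen after their values were seen.

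Glycosyltransferases and solute carriers were counted among the 127 genes that fell. Both families were picked because they stood out there, by symbol prefix, and the St6galnac prefix was added after a first count, so the odds ratios and p-values describe that choice and test nothing further. Of 76 glycosyltransferases among the 16637 genes tested, 7 fell, which is 5.51% of the falls against 0.457% of the genes tested (odds ratio 13.9, 95% interval 5.27 to 31.0, Fisher's exact test, two-sided, adjusted over both families p = 3.61e-06). They were B3galt5, B3gnt3, B3gnt5, Galnt12, Mgat4a, Mgat4c and St6galnac6, and B3galt5, which builds type 1 chains of glycans and is named after its values were seen, went from 418 ± 12.2 to 84.2 ± 11.7 CPM (SD, n = 2). Of 262 solute carriers 9 fell (odds ratio 4.90, 95% interval 2.16 to 9.77, exact p = 0.000183). These calls end without either IEC+/+ library.

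The lower level of the 127 genes may be technical or reflect tissue composition. After correcting each library for GC content the median log2 fold change of the 127 genes was -1.70, and after the length correction it was -1.69, against -1.70 before (quartiles -2.45 and -1.35), so the trends removed do not account for the size of the falls. Calls still dropped from 127 to 99 and 54, because adjusted p-values moved to at most 0.0595 and 0.0647. A larger share of normal mucosa in the IEC+/+ samples is a candidate explanation: of 141 genes at least 4-fold lower by mean level, chosen irrespective of p, 27.0% (95% exact interval 19.8% to 35.1%) had a log2 ratio of replicate 1 to replicate 2 in IEC+/+ under 0.19, against a colonocyte list median of 0.78 with 0.5 CPM added (0.93 with 0.1 CPM added, when the share was 27.7%). The interval treats genes as independent, though all were measured in the same IEC+/+ libraries, so it does not measure the spread between samples. Members of the colonocyte list, such as Clca4a, were among the 141 genes. A share under 10% was set as what mucosa would give and one over 50% as what would speak against it. A low share would not have singled out mucosa, since IEC+/+ tumours that differ in differentiation could also give it. Normal mucosa and the Gsk3b state of the epithelium therefore cannot be told apart here.

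The MHC class I and squamous pattern of IEC-/- replicate 2 was set against other tissue in the sample. Keratinised skin should bring Krt10, Lor and Sbsn, which together reached 0.731% of Krt5 plus Krt14 in that library, so skin is an unlikely source. If T cells and macrophages alone brought the class I transcripts, those lists should rise by as much as the MHC class I list. Their medians in this library over the mean of the other 3 were 0.19 and 0.11 on the log2 scale (upper quartiles 0.38 and 0.29), against 2.02 for MHC class I. This argues against T cells and macrophages at large as the only source. It does not bear on class I genes induced in other cells, which was not tested. Cytotoxic and NK cell genes (1.14, 7 of 8 higher) and neutrophil genes (0.85, 15 of 20 higher) were higher in this library, by less than the MHC class I list. So were interferon-stimulated genes (1.14, 28 of 30 higher) and MHC class II genes (0.66, 10 of 13 higher). A part played by cytotoxic cells, NK cells or neutrophils in the immune genes stays open, and these lists do not address the squamous genes. A squamous tissue without keratinisation, such as the border of the anal canal, and squamous change of the tumour itself also stay open. None of these was tested. An effect of the Gsk3b state on this pattern was not tested, since the other library of this group lacks the pattern.

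Gsk3b mRNA in IEC-/- was 0.921 of its level in IEC+/+, and several readings stay open. The counts may come from cells outside the epithelium, from epithelial transcripts that lack only the deleted part, or from incomplete deletion. A gene count does not separate these, so they cannot be told apart here. A chromosomal segment around Gsk3b that differs between the animals was tested by position: 2 of the 145 genes within 10 Mb changed (odds ratio 1.6, 95% interval 0.190 to 5.98, Fisher's exact test, two-sided, p = 0.362), which leaves the question open. They were Muc13 and Nr1i2, named after their values were seen. Nr1i2, a xenobiotic receptor gene whose annotated span begins 2264 bases beyond that of Gsk3b, fell from 38.0 ± 2.72 to 14.2 ± 2.35 CPM (SD, n = 2; edgeR adjusted p = 0.0479).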
